A study of Mus musculus with 17 samples.

How the data were processed

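The series holds 17 RNA-seq libraries of lung tissue from female mice, in 4 groups set by genotype and treatment. Wild-type (WT) C57BL/6J mice and FMO3 knockout mice on that background (written FMO3KO) received either subcutaneous bleomycin or phosphate-buffered saline (PBS). Per the labels, the dose was 10 mg/kg per day for 10 days at 5 days per week, the mice were 8 to 12 weeks old, and lungs were taken on day 22. Per the labels' protocols, RNA was isolated with a kit for fibrous tissue, the molecule was poly(A) RNA, and libraries were read with 150 paired-end cycles on a NovaSeq-6000. The labels give neither the time of day at collection nor the dates of library preparation, and do not say whether each library came from 1 mouse.

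The deposited values are expected counts (estimated counts) per gene, which the submitters made with cutadapt, STAR and RSEM on genome build GRCm38, per the labels; no versions and no annotation release are given. They have 1 column per library and Ensembl mouse gene IDs. A sentence of the labels' protocols on a filter of genes is cut short. The table still holds 19714 IDs with a count of 0 in every library, out of 55487 IDs. Of the deposited values, 5.83% were not whole numbers. Totals ranged from 30.6 to 49.7 M counts per library (M, mega), as in counts that were not normalised. Gene symbols were taken from a table of gene names, which matched 55141 IDs; the 346 unmatched IDs held 0.024% of the counts. Coordinates are on GRCm38. Where 2 IDs shared a symbol, the one with the higher mean count was used, and no read sharing between such IDs could be resolved from gene totals.

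Expected counts were rounded to whole numbers. Genes were kept by the default filter of edgeR (at least 10 counts in enough libraries for the smallest group, and 15 in total), which left 19163 genes, and libraries were scaled by the trimmed mean of M values. A negative binomial model with 1 coefficient per group was fitted with edgeR 4.0.16 in R 4.3.3, and quasi-likelihood F tests were made for 5 comparisons. These were bleomycin against PBS in WT, the same in FMO3KO, FMO3KO against WT under bleomycin, FMO3KO against WT under PBS, and the interaction, which is the bleomycin effect in FMO3KO minus that in WT. All tests are two-sided. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and "rose", "fell" or "past the threshold" means an adjusted p under 0.05. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of its F statistic. An SE given with a median over genes is taken over those genes instead. It holds no spread between libraries, and genes are not independent replicates. The p-values measure the spread between libraries. Levels are in CPM, counts scaled to a common library size by edgeR from the scaled totals, given as mean ± SD over the libraries of a group.

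Before the data were examined, 35 lists of genes were fixed from general knowledge of lung, fibrosis and the treatment, including markers of other tissues. All 667 listed symbols were found in the table. For 34 lists with at least 5 tested genes, camera (limma 3.58.1) compared each list with all other genes with a preset correlation of 0.01 between genes, with adjustment over the 34 lists; camera with an estimated correlation and fry were run as alternatives. Members were also counted with p-values "adjusted over the list alone". After the data had been examined, 5 lists were added and described by their levels only: squamous oesophageal epithelium, cartilage, brown fat, nuclear-retained RNAs and replication-dependent histones.

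Named genes followed a rule fixed before the data were examined. It takes, per comparison, the 6 highest and 6 lowest changes past the threshold with a mean of at least 1 CPM and no overlap between the groups (not required for the interaction), up to 4 members per list with the smallest adjusted p among those past the threshold, all genes past the threshold where 12 or fewer were, and 10 genes named in every comparison (Fmo3, Fmo1, Fmo2, Col1a1, Col3a1, Acta2, Timp1, Spp1, Cdkn1a and Sftpc). Unnamed loci and immunoglobulin or T cell receptor segments were left out of the first part. The text names part of the genes the rule takes, and that part was chosen after their values had been seen.

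Alternatives fixed beforehand were the size factors of DESeq2, upper-quartile scaling, no filter, a filter of a mean of at least 1 CPM, DESeq2 1.42.0 with its Wald test, limma-voom with quality weights, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. After the libraries had been seen to split within groups, 4 alternatives were added: a term for 2 classes of libraries by their Malat1 level, fits of the libraries of 1 class (for the counts of genes), the Malat1 and Neat1 level as a covariate, and leaving out the 3 libraries with most transcripts of other tissues. The block was not used in the reported fit, since libraries of the same number in different groups did not resemble each other: 9 of 24 such pairs had a correlation of their deviations over 0.1, and 3 of 17 libraries were closest to 1 with their own number.

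The steps were tested on simulated data drawn from the real genes' means, dispersions and library sizes, with 200 changed genes per comparison, of which 100 changed 2-fold and 100 changed 4-fold. With edgeR, 55 of the 2-fold and 88 of the 4-fold changes were recovered for bleomycin in WT (18938 genes), 51 and 87 for bleomycin in FMO3KO (18996 genes), 57 and 89 for genotype under bleomycin (18915 genes), 57 and 86 for genotype under PBS (18945 genes), and 29 and 68 for the interaction (18918 genes). The unchanged genes called were 12, 5, 7, 3 and 5. For bleomycin in WT, DESeq2 recovered 63 and 92, and limma-voom 54 and 86. The p53 list, raised by 0.5 on the log2 scale, was past the threshold in each of the 5 simulated comparisons, and no list free of changed genes was called by camera in any of them. Simulated genes were drawn independently and without library classes, so this cannot show how camera behaves where genes move together. In the real libraries the estimated correlation within the matrix list was 0.341.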

Results

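Transcripts were counted in 17 lung libraries of 4 groups: WT mice given PBS (4 libraries), WT mice given bleomycin (5), FMO3KO mice given PBS (4) and FMO3KO mice given bleomycin (4). Bleomycin is a DNA-damaging drug that is used to induce lung fibrosis in mice, and FMO3 is a flavin-containing monooxygenase known for oxidising trimethylamine. The series asks how loss of FMO3 bears on fibrosis in this model. Library totals were 30.7 to 36.8 M counts (M, mega) in WT PBS, 36.3 to 45.5 in WT bleomycin, 39.5 to 49.7 in FMO3KO PBS and 30.6 to 43.1 in FMO3KO bleomycin. Pairs of libraries of the same group had rank correlations over genes of 0.966 to 0.995, and genes are not independent replicates. WT bleomycin 5 stood apart in composition: its top gene, CT010467.1, took 10.9% of counts, against 4.93% or less for the top gene elsewhere. Its scaling factor, 0.859, was the lowest.

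Fmo3 (ENSMUSG00000026691, GRCm38 chromosome 1, 162953800 to 162984528, minus strand) was lower in each of the 8 FMO3KO libraries than in each of the 9 WT libraries. Its level was 32.2 ± 4.88 CPM (SD, n = 4) in WT PBS and 41 ± 11.2 (n = 5) in WT bleomycin, against 7.07 ± 1.08 (n = 4) in FMO3KO PBS and 4.16 ± 0.76 (n = 4) in FMO3KO bleomycin. Gene totals do not show which part of the gene the remaining reads came from. The neighbouring family members Fmo1 and Fmo2 were measured at 284 ± 24.2 and 1340 ± 85.8 CPM in FMO3KO PBS, against 236 ± 31.4 and 777 ± 98.1 in WT PBS. The Y-linked Ddx3y had a count of 0 in each of the 17 libraries, which the labels give as female. Of the 6 genes listed as checks of substrain and sex, 2 were tested, too few for a list test.

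**Figure D1:**
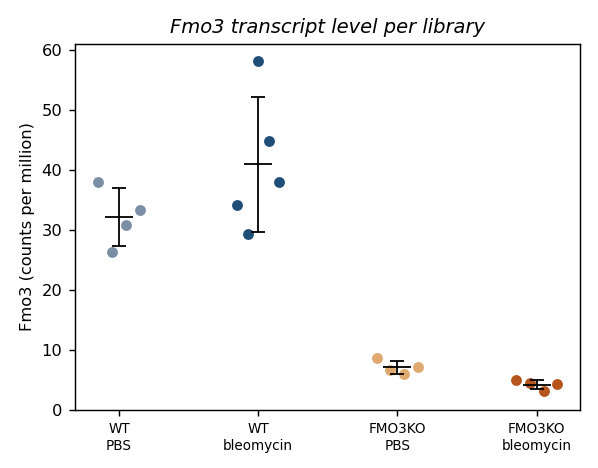
Level of Fmo3 in CPM for each library (points), with the mean and SD of each group (bars). The FMO3KO libraries lie between 3.1 and 8.56, and the WT libraries between 26.4 and 58.3.

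Libraries of the same group differed along an axis that the groups do not explain. Malat1, a nuclear long noncoding RNA, was at 9521 to 14940 CPM in 7 libraries and at 3880 to 7254 CPM in the other 10. The gap between these classes was 0.392 on the log2 scale and the next widest was 0.332, so the border is not sharp. The class with high Malat1 held 3 of 4 WT PBS, 2 of 5 WT bleomycin, 2 of 4 FMO3KO bleomycin and 0 of 4 FMO3KO PBS libraries. The median of 10 replication-dependent histone transcripts, which lack a poly(A) tail, was 1.07 to 4.5 CPM in that class and 6.35 to 24.2 in the other. Mitochondrial transcripts took 0.289 to 0.692% of counts in the high class and 0.553 to 1.72% in the other. The class with low Malat1 holds 1 WT PBS library and the other no FMO3KO PBS library, so comparisons within a class have 1 to 4 libraries per group, and a lone library is taken to vary like the others. Counts within a class and with the class as a term are given beside the pooled ones.

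**Figure D2:**
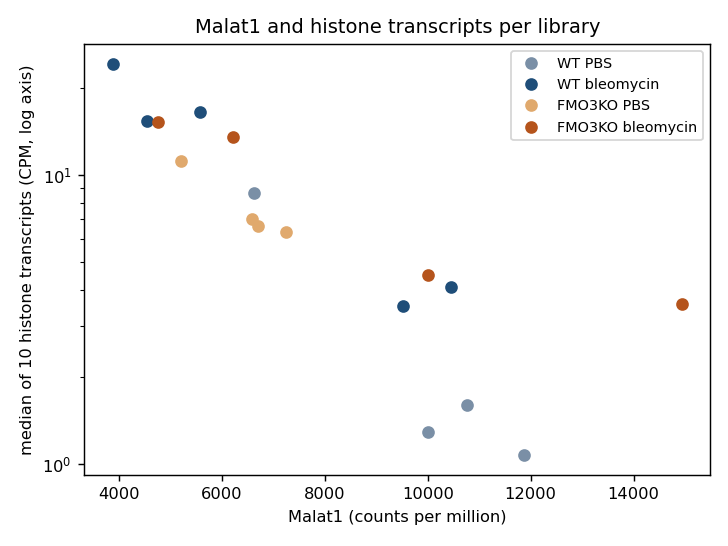
Level of Malat1 (CPM, horizontal axis) against the median level of 10 replication-dependent histone transcripts (CPM, log axis) for each of the 17 libraries, coloured by group. The 7 libraries with Malat1 at 9521 or more have histone medians of 4.5 or less, and the other 10 have medians of 6.35 or more.

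Some libraries held transcripts of tissues other than lung, or a high level of the B cell transcript Ighm. Krt4 and Krt13, keratins of the oesophagus and other squamous epithelia, were at 2970 and 1930 CPM in WT PBS 2 and at 202 and 149 in WT PBS 3. The median of 10 squamous oesophageal genes was 83.1 CPM in WT PBS 2. Rag1, a recombinase of developing lymphocytes, was at 29.5 CPM in WT bleomycin 2, where the median of the thymus list was 3.77. Ighm was at 825 CPM and the brown fat gene Ucp1 at 95.6 CPM in FMO3KO PBS 1, where the medians of the B cell, brown fat and cartilage lists were 30.2, 14.6 and 1.39 CPM. Cartilage and adipocyte transcripts were found in libraries of several groups: list medians were 1.72 and 28.7 CPM in FMO3KO PBS 4, 0.953 and 28.4 in WT bleomycin 2, 1.18 and 6.06 in WT bleomycin 1 and 0.927 and 13 in WT PBS 1.

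Bleomycin in WT mice raised transcripts of the p53 response, of cell division, of scar-associated macrophages and of the interferon response. Cdkn1a, the p53 target that stops the cell cycle, rose 5.09-fold from 47 ± 9.89 CPM (SD, n = 4) to 239 ± 70.1 (n = 5), and Eda2r, another p53 target, rose 6.58-fold. Spp1, which encodes osteopontin, rose 31.3-fold from 17.2 ± 2.61 to 539 ± 149 CPM (log2 4.97, SE 0.29, adjusted p = 3.01e-08). Of 19163 genes, 1977 rose and 1754 fell, and 798 and 474 of these changed at least 2-fold. The largest changes taken by the rule also included Saa3, an acute-phase protein, which rose 17.5-fold, and Bex2 and Hes2, which fell 13.5-fold and 11.5-fold.

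The p53, cell cycle, macrophage, interferon and complement lists were past the threshold in WT with a preset and with an estimated correlation. Of 26 p53 targets, 18 rose (20 adjusted over the list alone), among them Ccng1 at 2.83-fold and Psrc1 at 7.98-fold; adjusted p = 1.61e-22 preset and 0.000915 with an estimated correlation. All 26 cell cycle genes rose, as they did adjusted over the list alone, with Ccna2 at 4.04-fold and Ccnb1 at 3.48-fold (adjusted p = 6.98e-32 and 0.0189). Of 22 genes of profibrotic macrophages, 17 rose (19 rose and 1 fell adjusted over the list alone), with Gpnmb at 10.6-fold and Trem2 at 12.3-fold (adjusted p = 4.73e-28 and 0.0189). Of 28 interferon-response genes, 23 rose (23 adjusted over the list alone), with Isg15 at 2.54-fold and Oas2 at 3.4-fold (adjusted p = 1.2e-15 and 0.0128). Of 19 complement and acute-phase genes, 12 rose (13 rose and 1 fell adjusted over the list alone), with the receptor C3ar1 at 7.66-fold and Lcn2, an iron-sequestering protein, at 8.63-fold (adjusted p = 1.29e-07 and 0.0277).

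Matrix transcripts of WT lungs rose in part. Of 30 fibrillar collagen and matrix genes, 15 rose (18 adjusted over the list alone), among them fibronectin, Fn1, at 4.53-fold, tenascin, Tnc, at 3.96-fold and the cross-linking enzyme Loxl2 at 1.97-fold. Col1a1 and Col3a1 did not pass, with log2 changes of 0.36 (SE 0.23, adjusted p = 0.289) and 0.23 (SE 0.15, adjusted p = 0.284). The list had an adjusted p of 1.68e-10 with the preset and 0.165 with an estimated correlation. Of 20 genes of the TGF-beta response and myofibroblasts, 6 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.00492, and 0.165 with an estimated correlation). Ccn2 and Serpine1, both induced by TGF-beta, rose 3.81-fold and 2.64-fold, while the smooth muscle actin Acta2 had a log2 change of 0.24 (SE 0.21, adjusted p = 0.441). The protease inhibitor Timp1 rose 7.03-fold (log2 2.81). WT bleomycin 5 held 58.5 CPM of Timp1 against 11.3 to 21.2 in the other 4, and the log2 change was 2.21 without it, 2.2 with the replicate block and 2.15 with the Malat1 and Neat1 covariate, and passed in each. Of 20 senescence and secretory genes, 10 rose and 2 fell (12 and 2 adjusted over the list alone; adjusted p = 0.000512, and 0.199 with an estimated correlation), with the macrophage elastase Mmp12 at 55.8-fold higher and Igfbp3 at 4.52-fold lower. With the Malat1 and Neat1 covariate the log2 change of Mmp12 went from 5.8 to 5.03 and that of Lcn2 from 3.11 to 2.32.

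Markers of lung cell types moved apart within their lists in WT. Of 24 endothelial markers, 10 fell and 5 rose (10 and 5 adjusted over the list alone; adjusted p = 0.0025, and 0.223 with an estimated correlation), with the receptor Kdr and the peptide Apln falling 1.91-fold and 2.38-fold. Of 20 lipofibroblast and resident fibroblast markers, 10 fell and 2 rose (10 and 2 adjusted over the list alone; adjusted p = 0.000149, and 0.165 with an estimated correlation), with Inmt falling 2.66-fold and Pdgfra 1.6-fold. Of 20 alveolar type 2 markers, 3 fell and 2 rose (5 and 3 adjusted over the list alone), with Lpcat1, an enzyme of surfactant lipid synthesis, falling 1.53-fold and the alarmin Il33 rising 2.16-fold. Sftpc, the surfactant protein of type 2 cells, had a log2 change of −0.53 (SE 0.19, adjusted p = 0.066) and passed with the library class as a term (−0.67, adjusted p = 0.00268), the Malat1 and Neat1 covariate (0.0139), upper-quartile scaling (0.0415) and DESeq2 (0.037), and without WT PBS 1 or WT bleomycin 4 (0.0213 and 0.0251). Of 20 alveolar type 1 markers, 5 fell and 2 rose (5 and 2 adjusted over the list alone), with Hopx falling 1.64-fold. The tests of both alveolar lists gave an adjusted p of 0.981 and pointed down, against medians of 0.19 and 0.05 (log2). Of 20 transitional epithelial markers, 8 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 6.25e-05, and 0.165 with an estimated correlation). Of 20 airway markers, 2 fell and 1 rose (2 and 1 adjusted over the list alone; adjusted p = 0.981, pointing down against a median of 0.13), with Tppp3 falling 2.27-fold. Of 10 mesothelial markers, 3 fell (3 adjusted over the list alone; adjusted p = 0.0112, and 0.165 with an estimated correlation). Of 16 smooth muscle and pericyte markers, 2 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.792, pointing down against a mean of 0.05).

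Among immune cell markers in WT, 8 of 20 alveolar macrophage genes rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 5.72e-05, and 0.165 with an estimated correlation), with the chemokine Ccl6 at 4.9-fold. Of 20 genes of antigen presentation, 10 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 3.41e-05, and 0.274 with an estimated correlation), with the protease Ctss at 4.55-fold. Of 18 monocyte and neutrophil genes, 7 rose and 2 fell (7 and 2 adjusted over the list alone; adjusted p = 0.000512, and 0.311 with an estimated correlation). Of 23 B and plasma cell genes, 5 fell and 2 rose (5 and 2 adjusted over the list alone; adjusted p = 0.199, pointing down against a mean of 0.03). Of 24 T and NK cell genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.792).

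Clock, metabolic and stress lists were also counted in WT. Of 18 circadian and glucocorticoid-responsive genes, 8 rose and 3 fell (10 and 4 adjusted over the list alone; adjusted p = 0.0112, and 0.41 with an estimated correlation), with the clock repressor Per2 rising 2.44-fold and the clock genes Arntl and Nr1d1 falling 2.74-fold and 3.05-fold. Mean Per2 was 34 CPM in WT PBS, 83 in WT bleomycin, 148 in FMO3KO PBS and 87.5 in FMO3KO bleomycin. Collection times are not given, so for clock genes a difference in time of day cannot be told apart from a bleomycin effect. Of 24 genes of sterol and fatty acid synthesis, 7 fell (7 adjusted over the list alone; adjusted p = 0.00633, and 0.311 with an estimated correlation). Of 24 xenobiotic and oxidative stress genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.169), with the cystine transporter Slc7a11 at 4.89-fold. Of 6 FMO family genes, Fmo1 fell 1.45-fold (1 adjusted over the list alone; list adjusted p = 0.981), while Fmo2 and Fmo3 had log2 changes of 0.15 (SE 0.16) and 0.35 (SE 0.18). The Fmo1 call was lost with a replicate block (adjusted p = 0.0773), with the groups fitted alone (0.0864) and without WT PBS 1 or 4 or WT bleomycin 1 or 4 (adjusted p = 0.0597, 0.0759, 0.0544 and 0.0545). Of 13 mitochondrially encoded transcripts, 1 rose (1 adjusted over the list alone; adjusted p = 0.0112, and 0.596 with an estimated correlation). Members past the threshold were 3 higher and 1 lower of 26 unfolded protein and integrated stress genes, 4 higher of 26 nuclear genes of oxidative phosphorylation, 3 higher and 1 lower of 12 heat shock genes, and 1 higher of 15 immediate early genes. The adjusted p of these 4 lists was 0.169, 0.64, 0.404 and 0.981, and the counts adjusted over the list alone were 5 and 2, 4, 3 and 1, and 0. For tissues other than lung, 3 of 14 muscle markers fell, 1 of 10 blood markers fell, 1 of 7 thymus markers rose and 0 of 12 adipocyte markers passed. Adjusted over the list alone these counts were 5, 1, 1 and 0, and the adjusted p of the lists was 0.124, 0.981, 0.606 and 0.981. The test of the blood list pointed down against a median of 0.06. Rag1 rose 25.7-fold on the strength of WT bleomycin 2 and lost its call without that library (log2 2.22, adjusted p = 0.0778) and without WT PBS 1 (4.59, adjusted p = 0.0556), with limma-voom (2.65, adjusted p = 0.195), with the groups fitted alone (0.0726) and without the 3 libraries with other tissues (2.54, adjusted p = 0.108). Krt78, a squamous keratin, fell 146-fold on the strength of WT PBS 2, which held 167 CPM against 0.589 to 7.83 in the other 3 PBS libraries. Its log2 change went from −7.19 to −3.45 (adjusted p = 0.00319) without that library and to −3.7 without the 3 libraries with other tissues, and it did not pass with limma-voom (−2.91, adjusted p = 0.228). With the block, the class and the Malat1 and Neat1 covariate it was −5.32, −6.48 and −6.02, while Rag1 went from 4.68 to 3.94 with the block and 5.8 with the covariate.

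Rag1 and Fmo1 passed with levels that overlapped between the 5 bleomycin and 4 PBS libraries. Within the class with high Malat1 (2 against 3 libraries) 1502 genes passed, 1331 of them among the 3731, and within that with low Malat1 (3 against 1) 1481 passed, 1171 of them among the 3731. With the library class as a term 4886 genes passed, with the replicate block 2625, with the groups fitted alone 2005, and without the 3 libraries with other tissues 2480.

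Bleomycin in FMO3KO mice raised p53, cell cycle, macrophage and interferon transcripts and also collagen and elastin. Cdkn1a rose 5.51-fold from 37 ± 9.58 CPM (SD, n = 4) to 204 ± 26.2 (n = 4), Eda2r rose 6.51-fold and Spp1 rose 7.6-fold from 52.9 ± 14.1 to 402 ± 142 CPM. Elastin, Eln, rose 7.53-fold from 165 ± 64 to 1240 ± 647 CPM (log2 2.91, SE 0.4, adjusted p = 0.000243). With the library class as a term it was 2.31 (SE 0.29, adjusted p = 8.5e-05), and the FMO3KO bleomycin libraries stood at 1720 and 1880 CPM in the class with high Malat1 and at 679 and 690 in the other. Col3a1 rose 2.55-fold from 792 ± 141 to 2020 ± 191 CPM. Of 19163 genes, 1181 rose and 866 fell, and 422 and 271 of these changed at least 2-fold.

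The lists past the threshold in FMO3KO with an estimated correlation as well were p53, cell cycle, macrophage, interferon and blood. Of 26 p53 targets, 18 rose (19 adjusted over the list alone), with Ccng1 at 3.01-fold and Zmat3 at 2.41-fold; adjusted p = 4.48e-26 preset and 0.000338 with an estimated correlation. Of 26 cell cycle genes, 25 rose (26 adjusted over the list alone), with Cenpf at 4.33-fold and Top2a at 3.27-fold (adjusted p = 4.55e-35 and 0.0126). Of 22 profibrotic macrophage genes, 13 rose (18 adjusted over the list alone), with Gpnmb at 6.11-fold and Trem2 at 5.43-fold (adjusted p = 9.91e-20 and 0.0331). Of 28 interferon genes, 16 rose (20 adjusted over the list alone), with Isg15 at 2.08-fold and Oasl2 at 1.76-fold (adjusted p = 1.55e-14 and 0.0126). Of 10 erythroid and blood markers, 5 fell (7 adjusted over the list alone), with the globins Hba-a1 and Hba-a2 falling 4.11-fold and 3.01-fold (adjusted p = 5.37e-07 and 0.0303).

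Of 30 matrix genes in FMO3KO, 14 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 1.55e-14, and 0.0881 with an estimated correlation). Fibrillin, Fbn1, rose 2.58-fold, Tnc 3.66-fold and Col1a1 2.16-fold. Of 20 TGF-beta and myofibroblast genes, 2 rose and 4 fell (4 and 4 adjusted over the list alone; adjusted p = 0.958). The integrin Itgb6, which activates TGF-beta, rose 2.48-fold, while the contractile genes Cnn1 and Acta2 fell 2.07-fold and 1.73-fold. The Acta2 call was lost with the library class as a term (log2 −0.63, adjusted p = 0.0544), without the 3 libraries with other tissues (−0.69, adjusted p = 0.0992) and without any of FMO3KO PBS 1, 3 and 4 and FMO3KO bleomycin 2 and 3. Timp1 had a log2 change of 1.25 (SE 0.41, adjusted p = 0.0619) and passed with the class (1.6, adjusted p = 0.0138), the block (0.0129), the groups fitted alone (0.0108), DESeq2 (0.0142), limma-voom (0.00232) and the Malat1 and Neat1 covariate (0.00737). It also passed without the 3 libraries with other tissues (0.0362) and without WT bleomycin 2 or 5 or FMO3KO PBS 1 (0.0421, 0.00431 and 0.0469).

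For lung cell markers in FMO3KO, 3 of 24 endothelial genes fell (6 adjusted over the list alone; adjusted p = 0.00043, and 0.17 with an estimated correlation). Of 20 lipofibroblast and fibroblast markers, 5 fell and 1 rose (8 and 2 adjusted over the list alone; adjusted p = 0.0113, and 0.396 with an estimated correlation), with Inmt falling 2.49-fold and Pdgfra 1.55-fold. Of 16 smooth muscle markers, 4 fell (5 adjusted over the list alone; adjusted p = 0.0012, and 0.229 with an estimated correlation). Of 20 type 2 markers, 3 rose (3 adjusted over the list alone; adjusted p = 0.22), with Lpcat1 at 1.43-fold and Il33 at 1.81-fold. Sftpc had a log2 change of −0.18 (SE 0.21, adjusted p = 0.594), which was 0.039 with the class as a term. The Lpcat1 call was lost without any of FMO3KO PBS 1, 2 and 4 and FMO3KO bleomycin 2 and 3. Of 20 type 1 markers, 3 fell and 2 rose (4 and 2 adjusted over the list alone; adjusted p = 0.22). Of 20 transitional epithelial markers, 5 rose (13 adjusted over the list alone; adjusted p = 2.19e-06, and 0.0984 with an estimated correlation). Of 20 airway markers, 2 fell (3 adjusted over the list alone; adjusted p = 0.22), and of 10 mesothelial markers, 3 fell (5 adjusted over the list alone; adjusted p = 0.00281, and 0.0984 with an estimated correlation).

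For immune cells in FMO3KO, 5 of 20 alveolar macrophage genes rose and 3 fell (5 and 4 adjusted over the list alone; adjusted p = 0.255, pointing up against a mean of −0.25), with Ccl6 at 3.05-fold. Of 20 antigen presentation genes, 4 rose (6 rose and 2 fell adjusted over the list alone; adjusted p = 0.0283, and 0.6 with an estimated correlation), with Ctss at 4.14-fold. Of 19 complement and acute-phase genes, 3 rose (4 adjusted over the list alone; adjusted p = 0.00043, and 0.111 with an estimated correlation), with C3ar1 at 3.5-fold. Of 18 monocyte and neutrophil genes, 2 rose and 2 fell (2 and 3 adjusted over the list alone; adjusted p = 0.623, pointing up against a median of −0.21). Of 23 B and plasma cell genes, 5 fell (12 adjusted over the list alone; adjusted p = 0.00014, and 0.396 with an estimated correlation), with the antibody heavy chain Ighm falling 5.09-fold (log2 −2.35), and −1.15 (adjusted p = 0.0121) without FMO3KO PBS 1. Of 24 T and NK cell genes, 3 fell (5 adjusted over the list alone; adjusted p = 0.0051, and 0.534 with an estimated correlation).

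Among the other lists in FMO3KO, 4 of 6 FMO genes fell (4 adjusted over the list alone; adjusted p = 0.00162, and 0.213 with an estimated correlation): Fmo1 1.68-fold, Fmo2 1.51-fold, Fmo5 1.48-fold and the remaining Fmo3 signal 1.7-fold. The Fmo2 call was lost without the low-count filter (adjusted p = 0.0547), without the 3 libraries with other tissues (log2 −0.62, from −0.59, adjusted p = 0.0698) and in 8 of 17 fits that left out a library, and that of Fmo3 in 4. Of 24 xenobiotic and oxidative stress genes, 5 rose and 1 fell (6 and 3 adjusted over the list alone; adjusted p = 0.225, pointing up against a median of −0.10), with Slc7a11 at 3.61-fold, Srxn1 at 2.19-fold and Gclc at 2.17-fold. Of 18 circadian and glucocorticoid-responsive genes, 6 fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 0.000241, and 0.222 with an estimated correlation), with Per2 falling 1.69-fold, Nr1d1 2.07-fold and Dbp 2.04-fold. Dbp lost its call without FMO3KO bleomycin 2 or 3 (adjusted p = 0.0638 and 0.0648). Of 15 immediate early genes, 2 fell (8 adjusted over the list alone; adjusted p = 1.87e-05, and 0.396 with an estimated correlation), with Nr4a1 falling 4.73-fold. Of 20 senescence and secretory genes, 2 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.149). Of 24 sterol and fatty acid genes, 2 rose (6 rose and 6 fell adjusted over the list alone; adjusted p = 0.623, pointing up against a mean of −0.0064). Of 26 unfolded protein and integrated stress genes, 4 rose and 3 fell (8 and 5 adjusted over the list alone; adjusted p = 0.488), and 1 of 12 heat shock genes rose (1 adjusted over the list alone; adjusted p = 0.857, pointing up against a mean of −0.13). The phospholipase gene Plcd4 rose 8.33-fold. Of 12 adipocyte markers, 4 fell (11 adjusted over the list alone; adjusted p = 0.000338, and 0.454 with an estimated correlation). Among them was Ucp1, whose PBS libraries ranged from 0.967 to 95.6 CPM and whose call was lost with limma-voom (adjusted p = 0.246), without the 3 libraries with other tissues (0.0952) and without FMO3KO PBS 1 or FMO3KO bleomycin 2, 3 or 4 (0.0949, 0.0831, 0.0857 and 0.0673). Its log2 change went from −5.38 to −3.93 without FMO3KO PBS 1 and to −6.86 without FMO3KO bleomycin 1. It was −4.66 with limma-voom and −3.92 without the 3 libraries with other tissues. Of 14 muscle markers, 2 fell (2 adjusted over the list alone; adjusted p = 0.00427, and 0.516 with an estimated correlation). Members of the nuclear oxidative phosphorylation, mitochondrially encoded and thymus lists did not pass in edgeR (0, 0 and 2 adjusted over the list alone), with adjusted p of 0.225, 0.38 and 0.0786 for the lists.

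Ucp1 passed with levels that overlapped between the 4 bleomycin and 4 PBS libraries. Within the class with low Malat1 (2 against 4 libraries) 1102 genes passed, 855 of them among the 2047. With the library class as a term 2771 genes passed, with the replicate block 1843, without the 3 libraries with other tissues 1488, and with the groups fitted alone 4103.

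The bleomycin responses of both genotypes were compared gene by gene. In both, 702 genes rose and 354 fell, against 122 and 79.3 for independent calls, and 17 genes passed in opposite directions. Eda2r, Cdkn1a and Inmt changed by similar folds in both genotypes. Over all genes the log2 changes had a Pearson correlation of 0.229 and a Spearman correlation of 0.236; with the class as a term 1779 genes passed in both in the same direction, and the correlations were 0.399 and 0.54. Genes are not independent replicates, so these correlations carry no p.

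**Figure D3:**
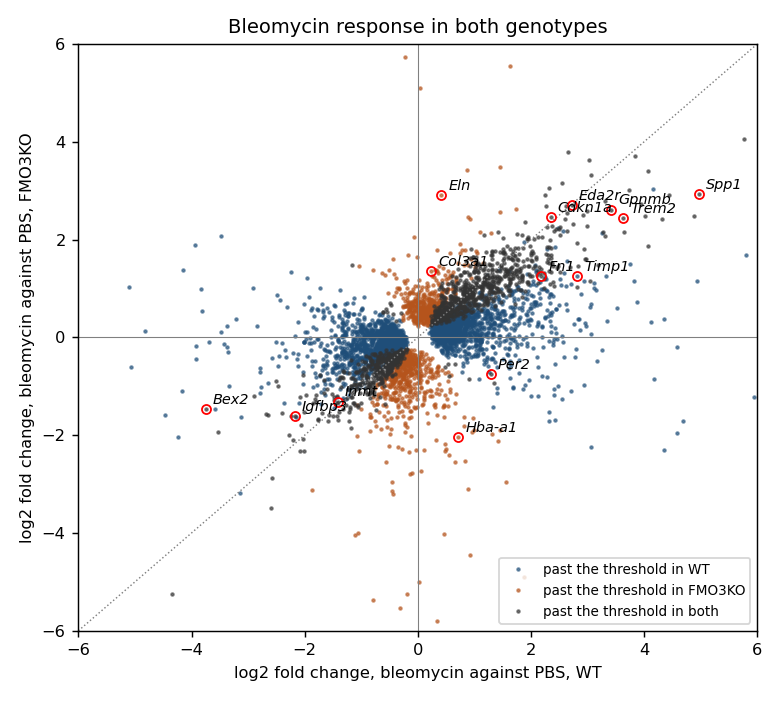
Log2 fold change for bleomycin against PBS in WT (horizontal) and FMO3KO (vertical), 1 point for each of the 4705 genes past the threshold in WT, in FMO3KO or in both; named genes are circled, the dotted line marks equal changes, and 21 such genes lie outside the axes. Eda2r and Cdkn1a lie near the line, and Eln and Col3a1 lie well above it.

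Between the genotypes under PBS, some clock genes and some matrix genes differed. Per2 was 4.35-fold higher in FMO3KO, at 148 ± 11.7 CPM (SD, n = 4) against 34 ± 2.26 (n = 4), Ciart was 4.87-fold and Per3 2.93-fold higher, and Arntl, which activates the Per genes, was 3.66-fold lower. Eln was 7.87-fold lower (log2 −2.98, SE 0.4, adjusted p = 0.000765), Col3a1 2.41-fold, Fbn1 2.33-fold and Col1a1 2.2-fold lower. Fitted with the class, the Eln difference was −2.26 (SE 0.3, adjusted p = 0.000894). Of 19163 genes, 304 were higher and 621 lower in FMO3KO, and 136 and 152 of these differed at least 2-fold. With the class as a term 205 genes passed, of which 161 were among the 925. Within the class with low Malat1 (4 against 1 libraries) 107 passed, 72 of them among the 925.

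Of 18 circadian and glucocorticoid-responsive genes, 10 were higher and 3 lower in FMO3KO PBS (11 and 3 adjusted over the list alone; adjusted p = 1.65e-15, and 0.0521 with an estimated correlation). Of 30 matrix genes, 8 were lower (10 lower and 1 higher adjusted over the list alone; adjusted p = 2.58e-05, and 0.863 with an estimated correlation). The Col1a1 call was lost with the class as a term (log2 −1.11, from −1.14, adjusted p = 0.0811), without the 3 libraries with other tissues (−1.07, adjusted p = 0.105) and without WT PBS 2 or FMO3KO PBS 2, 3 or 4 (0.0581 to 0.0806). The medians of the squamous list were 83.1 and 6.7 CPM in WT PBS 2 and 3 and 0.141 to 1.21 in the other 6 PBS libraries, and those of the B cell list were highest in FMO3KO PBS 1 and WT PBS 1 (30.2 and 18.7 CPM).

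Members of the TGF-beta, macrophage, blood, mitochondrial and FMO lists differed under PBS as well. Itgb6 was 2.19-fold lower and Ccn2 2.22-fold higher, the 2 of 20 TGF-beta genes that passed (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.583). The Ccn2 call was lost with the class as a term (log2 0.56, SE 0.13, from 1.15, SE 0.28; adjusted p = 0.0503), without the 3 libraries with other tissues (1.08, adjusted p = 0.162) and without any of WT PBS 1, 2 and 4 and the 4 FMO3KO PBS libraries (0.0589 to 0.124). Of 22 profibrotic macrophage genes, 2 were higher and 2 lower (2 and 3 adjusted over the list alone; adjusted p = 0.329), with Spp1 3.07-fold higher. Mmp12 was 11.5-fold higher on the strength of FMO3KO PBS 1, which held 40.8 CPM against 1.7 to 5.67 in the other 3, and its log2 difference went from 3.52 to 1.6 (adjusted p = 0.112) without that library. The Mmp12 call was also lost without WT PBS 1 or 2 or FMO3KO PBS 2 (0.0801, 0.123 and 0.0587), with limma-voom (2.05, adjusted p = 0.128), the block (0.0562), the class (3.03, adjusted p = 0.157) and the Malat1 and Neat1 covariate (2.9, adjusted p = 0.0705), and without the 3 libraries with other tissues (1.32, adjusted p = 0.233). Of 10 blood markers, Hba-a1, Hba-a2 and the platelet chemokine Ppbp were higher, by 3.66-fold, 2.16-fold and 2.63-fold (6 adjusted over the list alone; adjusted p = 7.14e-05, and 0.179 with an estimated correlation). These 3 calls were lost with the class as a term (log2 1.17, 0.97 and 1.01; adjusted p = 0.0647, 0.114 and 0.109) and without any of WT PBS 1 and 2 and FMO3KO PBS 2 and 4 (0.0503 to 0.0918). Those of both globins were also lost without FMO3KO PBS 1 (0.0553 and 0.0552) and without the 3 libraries with other tissues (0.165 and 0.133), where the log2 differences were 1.77 (from 1.87) and 1.14 (from 1.11). Of 13 mitochondrially encoded transcripts, mt-Co2 and mt-Co3 were higher by 2.6-fold and 5.52-fold (11 higher and 1 lower adjusted over the list alone; adjusted p = 1.06e-06, and 0.863 with an estimated correlation). The library classes differ in the mitochondrial share, and with the class as a term mt-Co2 went from 1.38 (SE 0.32) to 0.86 (SE 0.28, adjusted p = 0.157) and mt-Co3 from 2.46 (SE 0.68) to 0.98 (SE 0.63, adjusted p = 0.476). Both calls were also lost without the 3 libraries with other tissues (log2 1.11 and 2.48; 0.162 and 0.187) and without any of WT PBS 1 and 2 and the 4 FMO3KO PBS libraries (0.0574 to 0.149). The mt-Co3 call was lost as well without WT PBS 4 or WT bleomycin 4 (0.0832 and 0.0569), with the block (2.41, adjusted p = 0.0576) and with the Malat1 and Neat1 covariate (1.62, adjusted p = 0.0867). Of 6 FMO genes, Fmo2 and Fmo5 were 1.72-fold and 1.34-fold higher and Fmo3 was 4.55-fold lower (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.556, pointing up), while Fmo1 had a log2 difference of 0.27 (SE 0.17, adjusted p = 0.307) and passed with limma-voom (0.049). The calls of Fmo2 and Fmo5 were lost with the class as a term (log2 0.74 and 0.32; adjusted p = 0.103 and 0.227) and without the 3 libraries with other tissues (log2 0.81, from 0.79, and 0.43, from 0.42; 0.127 and 0.202). That of Fmo2 was also lost without WT PBS 2 or FMO3KO PBS 2, 3 or 4 (0.0607 to 0.0818). That of Fmo5 was lost without WT PBS 1 or 2, WT bleomycin 1 or 4, any FMO3KO PBS library or FMO3KO bleomycin 3 (0.0503 to 0.157), and with the block (0.0575), the Malat1 and Neat1 covariate (0.091) and no filter (0.0769).

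Some alveolar and endothelial markers differed under PBS. Lpcat1 was 1.72-fold lower, the 1 of 20 type 2 markers that passed (3 lower adjusted over the list alone; adjusted p = 0.917). Of 20 type 1 markers, 2 were higher and 2 lower (4 and 3 adjusted over the list alone; adjusted p = 0.334), with Akap5 and Ager 2.14-fold and 1.39-fold lower and the cytochrome gene Cyp2b10 2.07-fold higher. Of 24 endothelial markers 4 were lower (5 lower and 2 higher adjusted over the list alone; adjusted p = 0.62, pointing down against a median of 0.06), with Cldn5 1.53-fold and Tie1 1.58-fold lower. The immediate early gene Egr3, the hypoxia-related Hif3a and the acute-phase gene Lcn2 were 2.64-fold, 4.79-fold and 2.93-fold higher. With the class as a term the log2 differences of Cyp2b10, Lcn2, Ager, Cldn5 and Tie1 went from 1.05, 1.55, −0.47, −0.62 and −0.66 to 0.43, 0.73, −0.34, −0.48 and −0.35, and their calls were lost (adjusted p = 0.18, 0.14, 0.21, 0.123 and 0.304). Those of Akap5, Egr3 and Hif3a went from −1.1, 1.4 and 2.26 to −0.58, 0.9 and 1.39 and passed. Without the 3 libraries with other tissues none of the 9 genes from Lpcat1 to Lcn2 passed (0.0618 to 0.224), in fits with fewer libraries. Their log2 differences were then −0.65 for Lpcat1, −0.96 for Akap5, −0.38 for Ager, 1.11 for Cyp2b10, −0.44 for Cldn5, −0.39 for Tie1, 1.26 for Egr3, 2.03 for Hif3a and 1.14 for Lcn2.

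Of these 9 genes, Lpcat1, Egr3 and Hif3a passed in all 17 fits without 1 library. The call of Akap5 was lost without WT PBS 2 or FMO3KO PBS 1 or 4 (adjusted p = 0.0606, 0.0506 and 0.0566), and that of Cldn5 without WT PBS 1 or 2 or FMO3KO PBS 1, 2 or 4 (0.0518 to 0.0835). Those of Cyp2b10 and Lcn2 were lost without any of WT PBS 1, 2 and 4 and the 4 FMO3KO PBS libraries (0.0596 to 0.152), and that of Lcn2 also without WT bleomycin 4 (0.0545). The Ager call was lost without WT PBS 1 or 2, WT bleomycin 4 or any FMO3KO PBS library (0.0503 to 0.139), with the block (0.0614), with the Malat1 and Neat1 covariate (0.0748) and with no filter (0.0696). The Tie1 call was kept in 5 of 17 such fits, those without WT PBS 3, WT bleomycin 2, 3 or 5 or FMO3KO bleomycin 3, and its adjusted p was 0.0501 to 0.176 in the others. It was also lost with upper-quartile scaling (0.0573), with no filter (0.0569) and with the Malat1 and Neat1 covariate (0.0888).

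Transcripts of B cells and of other tissues differed between the PBS groups. Ighm was 3.69-fold higher, with 825 CPM in FMO3KO PBS 1, and its log2 difference went from 1.88 to 0.69 (adjusted p = 0.132) without that library and to 0.56 without the 3 libraries with other tissues. Its call was also lost without WT PBS 1, 2 or 4, WT bleomycin 4 or FMO3KO PBS 2 or 4 (0.0551 to 0.149), with the groups fitted alone (0.0682) and with the block (0.0582). With limma-voom it was lost at a log2 difference of 0.71 (adjusted p = 0.178), with the class at 1.76 (0.179) and with the Malat1 and Neat1 covariate at 1.57 (0.11). Krt4 and Acta1, of squamous epithelium and skeletal muscle, were 1030-fold and 579-fold lower on the strength of WT PBS 2, where they stood at 2970 and 256 CPM, against 2.8 to 202 and 0.294 to 30.2 in the other 3 libraries. The Krt4 difference was −8.05 with the class, with limma-voom −5.31, with the block −8.54 and with the Malat1 and Neat1 covariate −8.87; for Acta1 the last 2 gave −7.67 and −8.1. Without WT PBS 2 the log2 differences of both went from −10 and −9.18 to −6.6 (adjusted p = 0.0179) and −6.48 (adjusted p = 0.066). Without the 3 libraries with other tissues neither passed (−7.38 and −7.03; adjusted p = 0.0549 and 0.0631). The Acta1 call was also lost with limma-voom (−4.37, adjusted p = 0.0706), with the class as a term (−7.54, adjusted p = 0.0764) and without any FMO3KO PBS library (0.058 to 0.0743).

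Cdkn1a, Timp1, Acta2 and Sftpc did not pass (adjusted p = 0.302, 0.65, 0.408 and 0.775). The lists of alveolar macrophages, B cells, T cells, immediate early genes, sterol synthesis and transitional epithelium were also past the threshold with the preset (adjusted p = 0.0166, 0.0406, 0.0131, 0.0406, 0.0257 and 0.0242), the last 2 downwards. With an estimated correlation their adjusted p was 0.863, 0.913, 0.913, 0.913, 0.863 and 0.863. In these 6 lists 0, 1, 0 and 1 genes were higher in the first 4, 1 was lower in the sterol list, and 1 was higher and 4 lower in the transitional list (0, 2, 0, 1, 7, and 1 and 7 adjusted over the list alone). Among lists not past the threshold, 3 muscle genes, 2 airway genes and 2 unfolded protein genes were lower (4, 2, and 3 higher and 8 lower adjusted over the list alone; adjusted p = 0.213, 0.677 and 0.329). In the complement list 1 gene was higher and 1 lower (3 and 3 adjusted over the list alone; adjusted p = 0.499).

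Mmp12, Ighm and Col1a1 passed under PBS with levels that overlapped between the genotypes. Fmo3, Per2, Ciart, Per3, Arntl, Eln, Fbn1, Col3a1, Itgb6 and Spp1 passed in every alternative run for single genes (all but the fits within a class); 15 of the 32 named genes that passed did so with the class as a term, 11 without the 3 libraries with other tissues and 14 in all 17 fits without 1 library. The count of genes was 2953 without WT PBS 3, 356, 147 and 609 without WT PBS 1, 2 and 4, and 233, 167, 259 and 139 without FMO3KO PBS 1 to 4.

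**Figure D4:**
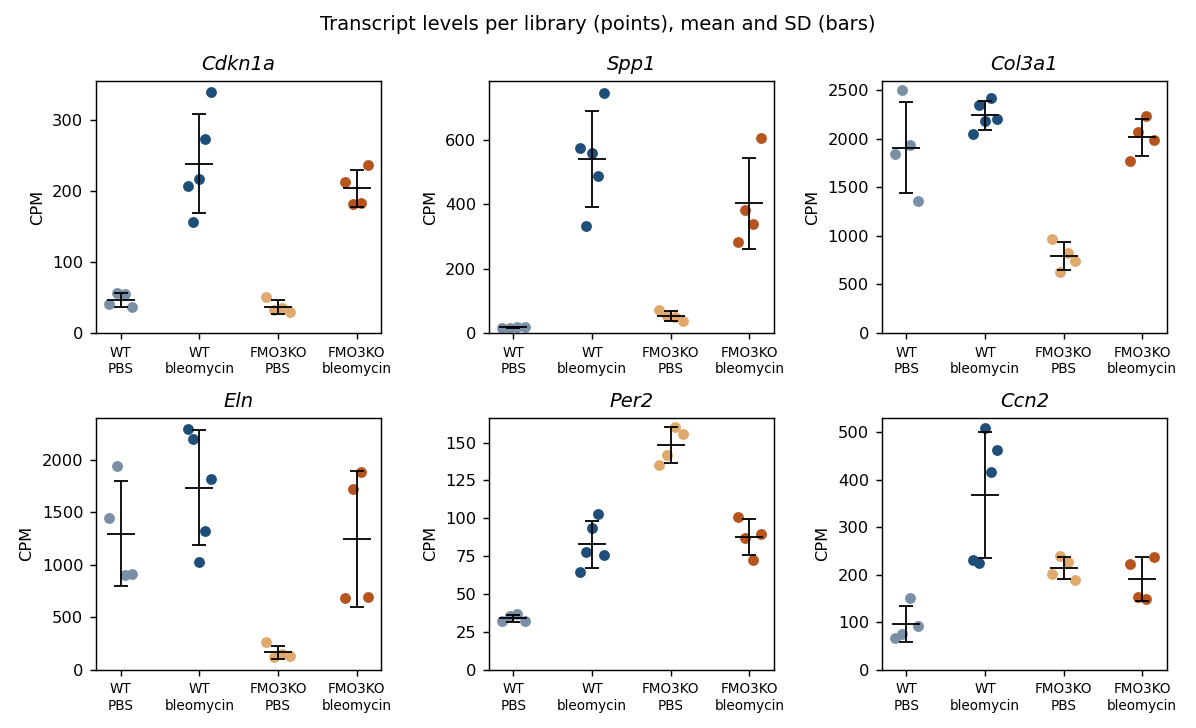
Levels of 6 genes in CPM for each library (points), with the mean and SD of each group (bars). Cdkn1a and Spp1 are higher under bleomycin in both genotypes, and the 4 FMO3KO PBS libraries lie lowest for Col3a1 (632 to 966) and Eln (124 to 260) and highest for Per2 (135 to 160).

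Under bleomycin, 5 genes differed between the genotypes. Fmo3 was 9.84-fold lower in FMO3KO (log2 −3.3, SE 0.21, adjusted p = 2.73e-07). The heart and slow muscle myosin Myh7 was 2.02-fold higher, the receptor kinase gene Ros1 2.61-fold higher, the endothelial peptide Apln 1.54-fold higher, and the transcription factor gene Tcf23 2.3-fold lower. At an unadjusted p under 0.05 there were 1271 genes, and 86 passed with DESeq2, 1 with limma-voom, 34 with the class as a term, 1 with the groups fitted alone, and 1 within each library class (2 against 3 and 2 against 2 libraries). The calls of Myh7, Ros1, Tcf23 and Apln were lost with limma-voom (adjusted p = 0.171, 0.171, 0.0659 and 0.11), with the groups fitted alone (0.15, 0.205, 0.361 and 0.42) and with the replicate block (0.0732, 0.166, 0.166 and 0.193). Without the 3 libraries with other tissues those of Ros1, Tcf23 and Apln were lost (0.124, 0.124 and 0.166), and that of Apln also with RLE scaling, upper-quartile scaling and no filter (0.0554, 0.0585 and 0.0806). The log2 differences hardly moved in these fits: 0.97 to 1.02 for Myh7 (from 1.01), 1.34 to 1.4 for Ros1 (from 1.39), −1.24 to −1.19 for Tcf23 (from −1.2) and 0.59 to 0.65 for Apln (from 0.63). Leaving out 1 library ended the call of Apln in 16 of 17 fits, of Tcf23 in 13 and of Ros1 in 5, and that of Myh7 and Fmo3 in none.

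Genes of fibrosis did not pass between the genotypes under bleomycin. The log2 difference was −0.39 (SE 0.23, adjusted p = 0.814) for Col1a1, −0.15 (SE 0.15) for Col3a1, −0.75 (SE 0.21, adjusted p = 0.402) for Acta2, −1.27 (SE 0.39, adjusted p = 0.472) for Timp1 (−0.67 without WT bleomycin 5 and −0.65 with the block), −0.42 (SE 0.24) for Spp1, −0.23 (SE 0.21) for Cdkn1a and 0.25 (SE 0.19) for Sftpc. Fmo1 and Fmo2 had differences of 0.057 (SE 0.16) and 0.046 (SE 0.16). Adjusted over the list alone, 9 of 30 matrix genes and 6 of 20 TGF-beta and myofibroblast genes were lower in FMO3KO bleomycin. The TGF-beta list had an adjusted p of 8.48e-07 with the preset and 0.0499 with an estimated correlation, with a median of −0.38, and the unfolded protein and integrated stress list 5.49e-05 and 0.0499, with a median of −0.17 (1 lower of 26 adjusted over the list alone). The matrix list had an adjusted p of 4.75e-13 and 0.159. A further 14 lists passed with the preset and had an adjusted p of 0.159 to 0.652 with an estimated correlation. Marker lists pointing down were among them: profibrotic macrophages (median −0.44, adjusted p = 8.23e-08), smooth muscle (−0.26, adjusted p = 1.03e-06), muscle (−0.79, adjusted p = 8.77e-07), transitional epithelium (−0.34, adjusted p = 7.24e-06), adipocytes (−1.71, adjusted p = 7.11e-05), monocytes and neutrophils (−0.44, adjusted p = 0.000114) and thymus (−0.39, adjusted p = 0.0291). The senescence, complement, immediate early, FMO and cell cycle lists also pointed down (adjusted p = 0.000114, 0.000697, 9.37e-05, 5.49e-05 and 0.0304; the FMO list against a median of 0.05), and the type 2 and sterol lists up (0.00631 and 0.0217). In these 14 lists Fmo3 was the 1 gene that passed, and adjusted over the list alone 5 smooth muscle, 3 thymus, 1 senescence, 1 complement and 1 FMO gene were lower. In 22 of 100 splits of these 9 libraries at least 17 lists passed with the preset.

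The interaction asks whether the bleomycin effect differed between the genotypes. It passed for 128 genes, 74 with a higher and 54 with a lower effect in FMO3KO, and 107 of these also differed between the genotypes under PBS while 3 differed under bleomycin. Clock genes had lower effects in FMO3KO: Per2 by 2.04 (log2, SE 0.19, adjusted p = 8.06e-05), Ciart by 1.62, Cry1 by 1.43 and Per3 by 1.2. Of the 18 circadian and glucocorticoid-responsive genes, 9 had a lower and 1 a higher effect (11 and 3 adjusted over the list alone; adjusted p = 4.72e-09, and 0.159 with an estimated correlation). Mean levels of Eln, Col3a1 and Fbn1 under PBS were 165, 792 and 347 CPM in FMO3KO and 1300, 1910 and 808 in WT. Under bleomycin they were 1240, 2020 and 895 CPM in FMO3KO and 1730, 2240 and 1020 in WT. From those lower PBS levels, Eln, Col3a1 and Fbn1 had higher effects, by 2.5 (SE 0.52, adjusted p = 0.0354), 1.12 and 1.03, the 3 of 30 matrix genes that passed (4 higher and 5 lower adjusted over the list alone; list adjusted p = 0.811, pointing up against a median of −0.09). Fitted with the class, these effects were 1.58 (SE 0.4), 1.08 (SE 0.24, from 1.12, SE 0.21) and 0.79 (SE 0.22, from 1.03, SE 0.22), and the 3 calls were lost (adjusted p = 0.112, 0.0638 and 0.137). They were also lost without the 3 libraries with other tissues (effects of 2.64, 1.09 and 1.0; 0.0756, 0.0509 and 0.168), with the Malat1 and Neat1 covariate (1.81, 1.14 and 0.87; 0.197, 0.0563 and 0.179) and, for Eln and Col3a1, with the block (2.49 and 1.09; 0.061 and 0.0801). Each call was lost without any of FMO3KO PBS 2 and 4 and FMO3KO bleomycin 2 and 3 (0.0543 to 0.122). Those of Eln and Fbn1 were also lost without any of WT PBS 1 and 2, WT bleomycin 3 and 4 and FMO3KO PBS 3 (0.0643 to 0.0982), that of Eln without WT bleomycin 5 (0.0542), and that of Fbn1 without WT PBS 4 or FMO3KO PBS 1 (0.0643 and 0.0753).

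Spp1, Ccn2 and Lpcat1 were among the other genes whose bleomycin effect differed. Spp1 had a lower effect in FMO3KO by 2.04 (SE 0.35, adjusted p = 0.0147), from a higher level under PBS, and was the 1 of 22 profibrotic macrophage genes that passed (12 lower and 1 higher adjusted over the list alone; adjusted p = 0.000619, and 0.495 with an estimated correlation). Ccn2 and Serpine1 had lower effects by 2.1 and 1.15 and Itgb6 a higher one by 0.94, among 20 TGF-beta and myofibroblast genes of which 3 were lower and 1 higher (5 and 1 adjusted over the list alone; adjusted p = 0.00393, and 0.405 with an estimated correlation). The calls of Serpine1 and Itgb6 were lost with the block (adjusted p = 0.0829 and 0.087), the class (log2 −0.99 and 0.7; 0.138 and 0.0843), the Malat1 and Neat1 covariate (0.164 and 0.128) and without the 3 libraries with other tissues (−1.17 and 0.9; 0.11 and 0.171). Both were also lost without any of WT PBS 1 and 2, WT bleomycin 3 and 4, FMO3KO PBS 1, 2 and 4 and FMO3KO bleomycin 2 and 3 (0.0518 to 0.11). That of Itgb6 was lost without WT PBS 4 as well (0.0702), and that of Serpine1 without WT bleomycin 5, FMO3KO PBS 3 or FMO3KO bleomycin 1 or 4 (0.0683, 0.0698, 0.0638 and 0.0658). The Ccn2 call was kept with the class (−1.37) and the Malat1 and Neat1 covariate (−1.48), and lost without the 3 libraries with other tissues (−2.16, adjusted p = 0.0689) and without WT PBS 2, FMO3KO PBS 2 or FMO3KO bleomycin 2 or 3 (0.0546, 0.0535, 0.0543 and 0.0623).

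Lpcat1 and Apln had higher effects by 1.13 and 1.04, and the immediate early genes Egr3 and Nr4a3 lower ones by 1.94 and 2.28. The Egr3 call was lost without FMO3KO bleomycin 2 or 3 (adjusted p = 0.0514 and 0.0558), and its effect was −1.31 with the class as a term. Hba-a1 and Hba-a2 had lower effects by 2.75 and 1.92, and the adhesion molecule Selp by 2.08. Without the 3 libraries with other tissues these 3 did not pass, with effects of −2.72, −1.86 and −2.11 (adjusted p = 0.169, 0.108 and 0.0689). The Hba-a1 call was also lost with the block (0.0787) and without any of WT PBS 1, 2 and 4, WT bleomycin 3 and 4, FMO3KO PBS 1, 2 and 4 and FMO3KO bleomycin 2 and 3 (0.0512 to 0.11), and that of Hba-a2 without FMO3KO bleomycin 3 (0.0514). The Hba-a1 effect was −2.03 with the class and −2.09 with the Malat1 and Neat1 covariate, and passed in both. Spon2, Fam124b and Bex2 had higher effects by 2.71, 2.64 and 2.28.

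A further 15 lists passed for the interaction with the preset, with an adjusted p of 0.159 to 0.734 with an estimated correlation. Of these the blood, adipocyte, immediate early, mitochondrially encoded and alveolar macrophage lists pointed down (adjusted p = 3.08e-05, 0.000619, 0.00046, 0.00118 and 0.00185), as did the monocyte, FMO, senescence, complement, smooth muscle and thymus lists (0.00189, 0.00475, 0.0204, 0.0204, 0.0204 and 0.0204) and the antigen presentation, B cell and T cell lists (0.0312, 0.0479 and 0.0485). The sterol list pointed up (0.00185). In these 15 lists 2 blood, 1 immediate early and 1 smooth muscle gene had lower effects past the threshold. Adjusted over the list alone, 8 sterol and 3 complement genes had higher effects, and 8 complement, 4 blood, 3 each of the monocyte, senescence, smooth muscle, FMO and adipocyte lists, 2 thymus and 1 immediate early gene lower ones. At least 18 lists passed in 25 of 100 splits of the libraries. Fmo3 itself had an interaction of −1.11 (SE 0.27, adjusted p = 0.0695) and Col1a1 of 0.75 (SE 0.34, adjusted p = 0.226), while Fmo1, Fmo2, Acta2, Timp1, Cdkn1a and Sftpc had adjusted p of 0.599, 0.139, 0.121, 0.167, 0.833 and 0.46. Fmo3 passed with DESeq2 (0.00726) and without WT bleomycin 2 (0.0373), Acta2 with DESeq2 (0.0375) and Fmo2 with limma-voom (0.0459). With the class as a term 78 genes passed, 64 of them among the 128, within the class with low Malat1 14 passed, 8 of them among the 128, and 24 passed without the 3 libraries with other tissues; of the 21 genes named here that passed, 12 did so in all 17 fits without 1 library.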

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

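The tests of the clock pattern, the test of matrix genes under bleomycin, the tests of GC content and depth, and the splits of the WT libraries for shared genes were chosen after the results had been seen; the other tests below were set down before their results were seen.

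Of 277 groups of values, 13 held a library far from the others of its group, and chance alone gives about 13.8 (1 in 20). WT bleomycin 5 had a total of 36.3 M counts, against 44.1 M or more in the other 4 libraries, an Fn1 level of 7760 CPM and an Acta2 level of 416 CPM. FMO3KO PBS 1 had Gpnmb at 31.2, Ctss at 155 and Top2a at 28.9 CPM. FMO3KO bleomycin 4 had C3ar1 at 39.7 and Il33 at 132 CPM. WT PBS 3 had Nr1d1 at 340 and Hba-a1 at 611 CPM. Ccng1 stood at 248 CPM in WT bleomycin 3, Plcd4 at 1.05 CPM in FMO3KO PBS 3 and mt-Co3 at 69.3 CPM in WT PBS 1.

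The interaction test called 21 named genes, 16 also with the class and 11 in every alternative. Of 128 calls 107 differed under PBS and 3 under bleomycin. The effect (log2, FMO3KO minus WT) was −2.04 (Per2 and Spp1), −1.62 (Ciart), −1.2 (Per3), −1.43 (Cry1), −2.1 (Ccn2) and −1.15 (Serpine1). It was −1.94 (Egr3), −2.28 (Nr4a3), −2.08 (Selp), −2.75 (Hba-a1) and −1.92 (Hba-a2). It was 2.5 (Eln), 1.12 (Col3a1), 1.03 (Fbn1), 0.945 (Itgb6), 1.13 (Lpcat1), 1.04 (Apln), 2.71 (Spon2), 2.64 (Fam124b) and 2.28 (Bex2).

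Under PBS, 13 circadian and glucocorticoid-responsive transcripts differed between the genotypes, with a median change of 1.48 (log2, SE 0.15 over the transcripts) in the called direction. Library class as the whole cause is argued against by a median of 1.35 (SE 0.18) with the class as a term, where 12 calls were kept. A genotype effect of like size in both treatments is argued against by a median of 0.179 (SE 0.12) under bleomycin. The 13 were chosen by their difference under PBS, which favours a larger median there. The interaction holds the same PBS difference, so its 10 calls are no separate support. Under bleomycin too, 8 of 9 Per, Dbp and Nr1d type transcripts were higher and 3 of 3 Arntl type transcripts lower, so a smaller effect under bleomycin stays open. The time of day at collection stays open and cannot be told apart from a clock difference by genotype in untreated mice: 8 of 9 Per, Dbp and Nr1d type transcripts were higher and 3 of 3 Arntl type transcripts lower, which both predict, and the labels give no collection times. For clock genes in the bleomycin and interaction comparisons, time of day was not tested and stays open as well. Age, given as 8 to 12 weeks, was not tested.

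Under PBS, 8 collagen, elastin and fibrillin transcripts were lower in FMO3KO, with a median fall of 1.11 (log2, SE 0.33 over the transcripts). Library class as the whole cause is argued against by a median of 0.985 (SE 0.23) with the class as a term, though 3 of the 8 calls ended. Squamous tissue in WT PBS 2 as the whole cause is argued against by a median of 0.931 (SE 0.31) without that library, where 4 of the 8 calls were kept. The 8 were chosen by their fall in these same PBS libraries, which favours larger medians under PBS in both of these fits. Both arguments therefore hold for the transcripts whose calls were kept. A genotype effect present in both treatments stays open, since under bleomycin all 8 were lower by a median of 0.281 (SE 0.059), and 3 were called for the interaction. Age was not tested here either.

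Libraries of the same group fell into 2 classes by Malat1, between which 8290 genes passed, 3632 higher and 4658 lower in the 7 libraries with high Malat1. Depth is argued against by mean totals of 38.7 and 40.5 M counts (exact permutation p = 0.523, two-sided). The share of RNA without a poly(A) tail stays open: 15 small RNAs of that kind had a median difference of −1.02 (SE 0.43 over these RNAs). Of them 11 were lower, fewer than the test had asked for, while all 10 histones were lower. GC share and class difference had a rank correlation over genes of −0.309, just past the bound of a first test, which came out in favour of GC. A second test, chosen after that, took out each library's GC trend and gave 8958 genes, against 8290 with the trend left in. The count did not fall, which argues against GC as the whole cause, while the correlation over genes stays. No biological explanation was tested: 3 of 4 WT PBS and 0 of 4 FMO3KO PBS libraries were in the high class, so a part played by genotype under PBS stays open, while WT PBS and both bleomycin groups had libraries in both classes.

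Other splits of the same libraries were fitted to see whether chance can be excluded. For bleomycin in WT it can for 3731 genes: 2 of 100 splits gave as many, the real one included, and the highest other gave 5884. That split set exactly the 5 libraries with high Malat1 against the other 4, which points to the library classes as a structure of the samples. With the class as a term 4886 genes passed. Chance can be excluded for bleomycin in FMO3KO (2047 genes, 1 of 35 splits, highest other 0) and genotype under PBS (925 genes, 1 of 35, highest other 10). With 35 splits, 1 of 35 is the smallest share possible, so neither exclusion can be stricter. No share was adjusted over the comparisons. Under PBS the real split set 3 libraries with high Malat1 against 0, as did some others, which gave 0 genes. In that comparison 205 genes passed with the class as a term and 69 without the 3 libraries with other tissues. For the interaction (128 genes, 1 of 100, highest other 24) the splits cannot decide. They mixed bleomycin and PBS libraries within each genotype, which breaks up the bleomycin effect itself and not only its difference between genotypes. For the genes shared by both genotypes (1056) splits of both genotypes decide nothing (1 of 100, highest other 0), since the other FMO3KO splits call 0 genes and leave none to share. With the FMO3KO calls kept and the WT libraries alone split, chance can be excluded for WT groups unrelated to treatment (1 of 100, highest other 182; 601 with the FMO3KO calls fitted again in each split). It cannot be excluded for the count of genes for genotype under bleomycin, where 5 genes passed and 6 of 100 splits gave as many. The highest other split, which set the 4 libraries with high Malat1 against the rest, gave 6666. The remaining ones with as many gave 2611 to 3437 and had 0 libraries with high Malat1 in 1 group. So each of these splits followed the library classes. With the class as a term 34 genes passed in this comparison. The splits weigh the count and not single genes such as Fmo3, the targeted gene (adjusted p = 2.73e-07 by the F test). For counts of gene lists with the preset correlation, chance cannot be excluded: as many were found in 18 of 100 splits in WT (18 lists, highest other 23), 6 of 35 in FMO3KO (20, highest other 21), 22 of 100 for genotype under bleomycin (17, highest other 21), 22 of 35 for genotype under PBS (10, highest other 17) and 25 of 100 for the interaction (18, highest other 24).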

How the results depend on the processing

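The library class as a term, fits within a class, the Malat1 and Neat1 level as a covariate, and leaving out WT PBS 2, WT bleomycin 2 and FMO3KO PBS 1 together were chosen after the data had been seen; the other alternatives were planned. Where a result changed, the cause was not tested, except that fits with fewer libraries have less power by construction. Over all named genes and alternatives except the fits within a class, which gave counts of genes, 4368 values kept their direction and their side of the threshold, 354 lost a call, 21 gained one and 16 reversed.

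For bleomycin in WT, 3731 genes became 2005 with the groups fitted alone, 2480 without the 3 libraries with other tissues, and 1481 and 1502 within the classes with low and high Malat1. For bleomycin in FMO3KO, 2047 became 5079 with limma-voom, 4103 with the groups fitted alone 3554 with the Malat1 and Neat1 covariate and 1102 within the low class. For genotype under bleomycin, 5 became 8 with a filter of mean CPM at least 1, 86 with DESeq2, 1 with limma-voom, 1 with the groups fitted alone, 2 with the replicate block, 34 with the 2 library classes as a term, 9 with the Malat1 and Neat1 covariate, 2 without the 3 libraries, and 1 within either class. For genotype under PBS, 925 became 2786 with DESeq2, 7555 with limma-voom, 2706 with the groups fitted alone, 205 with the class, 599 with the Malat1 and Neat1 covariate, 69 without the 3 libraries and 107 within the low class. For the interaction, 128 became 827 with DESeq2, 850 with limma-voom, 63 with the replicate block, 78 with the class, 59 with the Malat1 and Neat1 covariate, 24 without the 3 libraries and 14 within the low class. The 1056 genes shared by both genotypes became 1591 with limma-voom, 1779 with the class and 1716 with the Malat1 and Neat1 covariate.

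Leaving out 1 library in turn gave 2521 to 4123 genes for bleomycin in WT and 705 to 1137 shared genes. For bleomycin in FMO3KO it gave 1078 to 2336, with 1205, 1331 and 1091 without FMO3KO PBS 2, 3 and 4 and 1094 and 1078 without FMO3KO bleomycin 2 and 3. For genotype under bleomycin it gave 2 to 6, with 2 without WT bleomycin 2 or FMO3KO bleomycin 1, 3 or 4, and 3 without WT PBS 1 or 4, WT bleomycin 3, FMO3KO PBS 2, 3 or 4 or FMO3KO bleomycin 2. For genotype under PBS it gave 139 to 2953, with 356, 147, 2953 and 609 without WT PBS 1 to 4 and 233, 167, 259 and 139 without FMO3KO PBS 1 to 4. For the interaction it gave 43 to 218, with 66, 218 and 71 without WT PBS 2, 3 and 4, 216, 198, 74 and 85 without WT bleomycin 1 to 4, 55, 58 and 48 without FMO3KO PBS 1, 2 and 4, and 45 and 43 without FMO3KO bleomycin 2 and 3.

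Gene lists past the threshold went with an estimated correlation from 18 to 5 in WT, 20 to 5 in FMO3KO, 17 to 2 for genotype under bleomycin, 10 to 0 for genotype under PBS and 18 to 0 for the interaction. With fry they were 2 for genotype under bleomycin, 2 under PBS and 3 for the interaction.

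The reversed values were all of genes not past the threshold. Acta2 for bleomycin in WT was −0.109 with the Malat1 and Neat1 covariate and −0.00198 to 0.371 with 1 library left out (lowest without WT bleomycin 5), and for genotype under PBS −0.000572 with the class. Timp1 for genotype under PBS was −0.207 with the class and −0.0909 with the Malat1 and Neat1 covariate. Sftpc was 0.0386 for bleomycin in FMO3KO with the class, and for genotype under PBS 0.203 with limma-voom and −0.245 to 0.105 with 1 library left out (highest without WT PBS 3). For genotype under bleomycin, Fmo1 was −0.0498 with the replicate block, −0.0504 and −0.0043 without WT bleomycin 5 and FMO3KO bleomycin 1, and up to 0.206 with 1 library left out. Fmo2 was −0.0646 with the block, and −0.0102, −0.0653 and −0.0296 without WT bleomycin 1, WT bleomycin 5 and FMO3KO bleomycin 1, and up to 0.185 with 1 library left out. Cdkn1a for the interaction was −0.00296 to 0.307 (lowest without WT bleomycin 2). At this depth and number of libraries, 2-fold changes were recovered in simulated data for 51 to 57 of 100 genes in the comparisons of groups and for 29 of 100 in the interaction. Those data held 200 changed genes, drawn independently and without library classes. For genotype under bleomycin 158 genes were called there, against 5 in the real libraries. With fewer calls the Benjamini-Hochberg adjustment is stricter, so recovery in that comparison can be lower than simulated.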
